A study of Arabidopsis thaliana with 79 samples.

How the data were processed

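The study measured messenger RNA in 7-day-old Arabidopsis thaliana Col-0 seedlings with 79 Affymetrix ATH1 arrays. Per the labels' protocols, seedlings grew at 23 °C under 16 h of light and were held for 2 h in argon (hypoxia) or in air (control). Plants carried an epitope-tagged ribosomal protein L18 under one of 13 promoters, the tagged ribosomes were immunopurified from root or shoot extracts, and the RNA bound to them was extracted. This RNA is called polysomal RNA here. Total RNA came, per the labels' protocols, from the clarified extract of the plants in which the 35S promoter (p35S) drives the tag. Between 15 and 100 ng of RNA went through 2 cycles of cDNA synthesis before labelling.

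The deposited values are log2 signals. Per the submitters' processing notes, the authors made them with RMA in the R package affy, for which no version was given; RMA includes background correction, quantile normalization of probes and median polish. Whether all arrays were normalized together is not stated. The table holds 22810 probe sets. The 64 AFFX control probe sets were left out of the tests, which leaves 22746, and no other filter was applied. Values lay between 3.31 and 15.16, array medians between 6.31 and 6.64, and array means between 6.67 and 6.91. The lowest correlation between replicate arrays of a group was 0.973 and the highest 0.994, and no 2 arrays were identical. The number of arrays limits the precision of each value.

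Probe sets took names from the platform annotation, matched to the RefSeq annotation of assembly TAIR10.1. A single gene was assigned to 13513 probe sets, several genes to 503, and 8730 probe sets carry no name here, so 13355 genes could be named. The labels state no genome build for the array, and no coordinates are given. For gene lists, each gene was represented by the probe set with the highest mean over all arrays.

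The 79 arrays form 36 groups defined by organ, condition and RNA population: 30 groups of 2 arrays, 5 of 3 and 1 of 4. The labels describe replicates as independent biological experiments, so p-values measure the spread between biological samples. One linear model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated variances (43 residual and 4.48 prior degrees of freedom). The spread is thus pooled over groups, and a group of 2 is assumed to vary like the others. From this model came 42 contrasts: hypoxia minus control in 17 populations, polysomal minus total RNA in 4 organ and condition settings, the change of that difference under hypoxia (loading) in both organs, each promoter line minus p35S under control conditions in 15 organ and line settings, and root minus shoot hypoxia response in 4 populations. A pair of F-tests asked whether the hypoxia response differs among the 8 root and the 5 shoot promoter lines other than p35S. P-values were adjusted per contrast by Benjamini-Hochberg over 22746 probe sets. A probe set was called when its adjusted p was under 0.05 and its absolute log2 difference at least 1, a change of at least 2-fold. For the F-tests the range of the log2 responses had to be at least 1. Errors are standard errors (SE) of the modelled difference or, for group means, standard deviations (SD).

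Whether replicate numbers pair control and hypoxia arrays was checked by correlating their deviations from the group means. The correlations were 0.26, 0.54 and 0.72 for the root total RNA pairs and 0.36, 0.22 and 0.60 for the shoot total RNA pairs. In the other populations only 2 numbers are shared, which fixes the correlation to be nearly equal for both pairs, and it ranged from −0.23 in root pRPL11C to 0.59 in root pSHR. The main model has no pair term. A term for the replicate number was one of the alternatives. For hypoxia and root-shoot contrasts and the F-tests it paired control and hypoxia arrays within a population. For polysomal, loading and enrichment contrasts it joined like-numbered arrays of different populations within an organ and condition. There it did not pair control with hypoxia.

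Comparisons, thresholds, gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. Genes named in the text are the members of the fixed lists, the 10 largest rises and falls of the total and p35S hypoxia contrasts, the 5 largest of each other contrast, and at most 30 genes called in every root, every shoot or every population. Ranked genes had to have a probe set with 1 gene and arrays that did not overlap between the compared groups, a condition not asked of root-shoot differences, loading and F-tests. Genes without a symbol in the annotation appear under their locus identifier.

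There were 20 fixed lists with up to 27 listed genes, many of which have no named probe set. The lists for shoot epidermis and cuticle, for xylem and stele, and for the tagged ribosomal protein had 0 measured members. Those for ethylene, low energy and root endodermis had 1 member each, so no list test was run. A further 10 longer lists were made after the annotation and before any contrast was seen, and lists of 69 plastid-encoded and 26 measured seed maturation genes were made after the contrasts were seen. The lists of oxygen sensing and hypoxia markers and of earlier reported hypoxia-induced loci hold genes that earlier work, including this study, chose for their hypoxia response. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment within each family of tests, and again with the correlation estimated for each list. Fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, was run as a further test. For the 8 fixed lists planned for hypoxia, camera called 55 of 136 tests (41 higher, 14 lower), of which 46 held with the estimated correlation and 53 after quantile normalization, and fry called 69. For the 7 fixed lists planned for enrichment it called 6 of 105 tests, of which 4 held with the estimate, and fry called 39. The added lists, together with the fixed lists not planned for that comparison, made further families of 18 lists for hypoxia and 19 for enrichment, where camera called 105 of 306 and 83 of 285 tests, of which 27 and 8 held. All lists were also tested on the other contrasts, where 34 of 104 polysomal, 7 of 52 loading and 29 of 104 organ tests were called and 8, 0 and 9 held. No median of a called list changed sign after quantile normalization. None did after adding 50 to the linear values, but that step keeps the order of values and can hardly reverse a sign.

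The model was tested on simulated data, drawn around each probe set's mean over all arrays with its pooled spread. Noise was normal and independent, with no pairing, so the model's assumptions held by construction. In the real groups the median SD over probe sets ran from 0.099 (hypoxic shoot pKAT1) to 0.239 (hypoxic shoot total RNA). The shares below thus hold only where a common spread holds. Of 200 probe sets shifted by log2 1.5, it called 92.5% in the root p35S hypoxia contrast, 97.5% in root total RNA, 85.0% and 75.0% in the root and shoot loading contrasts, and 79.0% in the p35S organ contrast. At log2 2 these shares were 99.0%, 99.0%, 95.0%, 93.5% and 91.5%. No call had the wrong sign, and there were between 0 and 13 false calls per simulation. The F-tests called 97.5% and 99.5% of probe sets shifted by log2 3 in 1 line.

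Alternatives were quantile normalization of the deposited values, leaving out probe sets whose group means all lie under 6.47 (15182 pass), adding 50 to the linear values, fitting each organ alone, a term for the replicate number, the mean of the other promoter lines in place of p35S as reference, and leaving out each array. Chosen after seeing the data were a crossed pairing of root pRPL11C, leaving out root total replicate 4 or shoot total replicate 3, and leaving plastid-encoded probe sets out of the enrichment counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3. The cell types in which each promoter is active are not in the labels and are given from general knowledge. Sequence-level data were not used here.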

Results

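The data are log2 expression values of 22746 probe sets on 79 arrays, 47 from roots and 32 from shoots. Each array carries polysomal RNA of one promoter line or total RNA, after 2 h of hypoxia or in air. The p35S promoter is, from general knowledge, active in nearly all cells, but how evenly it tags them was not tested. From general knowledge, pSCR is active in the endodermis, pSHR and pWOL in the stele, pGL2 in non-hair epidermis and trichomes, pSUC2 in companion cells of the phloem, pSultr2;2 in the phloem, pCO2 in the meristematic cortex, pPEP in the cortex, pRPL11C in dividing root cells, pRBCS in mesophyll, pCER5 in epidermis and pKAT1 in guard cells. Both conditions exist for 10 root and 7 shoot populations, while pSultr2;2 has control arrays only. In roots there are 4 control and 3 hypoxic total RNA arrays, 3 control and 2 hypoxic arrays for p35S and for pGL2, and 2 arrays in each other group. Shoots have 3 total RNA arrays per condition and 2 arrays in each other group.

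The first question was which transcripts change in whole roots, and in the polysomal RNA of roots, when oxygen is withdrawn. In root total RNA AT4G10270 rose by 8.15 ± 0.25 (SE, 3 hypoxic and 4 control arrays, adjusted p 1.35e-29), from a mean of 4.73 ± 0.21 (SD) to 12.89 ± 0.12. Its control mean lay near background, which limits how exactly the size of this rise is known. AT5G10040 rose by 7.91 ± 0.31, the trihelix transcription factor gene AT3G10040 by 6.32 ± 0.26, and the calmodulin-like gene CML38 by 5.52 ± 0.29. AT4G33560, AT3G27220, AT1G19530, AT4G24110, AT2G17850 and AT1G33055 completed the 10 largest rises, at 5.25 to 6.10. Falls were smaller. AT4G25250 fell by 2.69 ± 0.24, the expansin gene EXPA15 by 2.13 ± 0.35, the cellulase gene GH9C2 by 1.92 ± 0.31 and the root hair expansin gene EXPA18 by 1.89 ± 0.24. In p35S polysomal RNA (2 hypoxic and 3 control arrays) AT5G10040 rose by 8.01 ± 0.37, AT4G10270 by 7.85 ± 0.30 and AT4G33560 by 6.96 ± 0.27, and the falls included AT5G51470 (−2.34 ± 0.17), AT1G12320 (−2.29 ± 0.21) and AT4G25250 (−2.20 ± 0.29). Tested with limma and Benjamini-Hochberg adjustment, 485 probe sets were higher and 281 lower in total RNA, and 450 were higher and 195 lower in p35S RNA. Adding 50 to the linear values gave 355 higher and 125 lower in total RNA. The p35S count of 645 rested on single arrays: it was 313 without hypoxic replicate 3 and 1002 without hypoxic replicate 1.

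**Figure D1:**
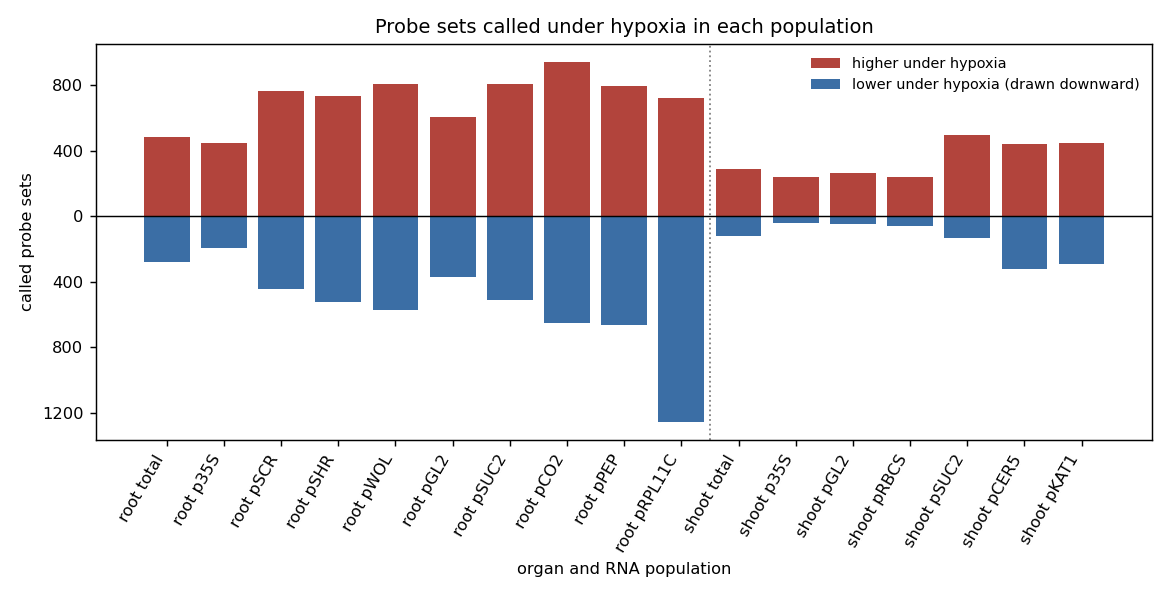
Called probe sets (vertical axis, count) in each organ and RNA population; red bars show those higher and blue bars, drawn downward, those lower under hypoxia. Root pRPL11C has 1255 lower and 725 higher, whereas shoot p35S has 38 lower and 239 higher.

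Among the root promoter lines, AT5G10040 rose by between 7.42 (pCO2) and 8.59 (pRPL11C) and AT4G10270 by between 7.12 (pSCR) and 8.57 (pRPL11C). AT1G19530 reached 7.60 ± 0.35 in pPEP and AT4G24110 7.30 ± 0.36 in pRPL11C (2 arrays per condition). The largest fall was that of EXPA15 in pRPL11C, −3.71 ± 0.46 (adjusted p 3.04e-08), and it fell by 3.49 ± 0.46 in pWOL. GH9C2 fell by 3.53 ± 0.41 in pRPL11C, and AT1G49200 by 3.67 ± 0.41 in pSUC2. AT3G45700 fell by 3.58 ± 0.25 in pSUC2 and by 3.28 ± 0.25 in pCO2, where AT1G64880 fell by 3.17 ± 0.31. AT4G18630 fell by 2.81 ± 0.37 in pWOL and AT1G12320 by 2.94 ± 0.21 in pGL2. Called counts were 768 higher and 443 lower in pSCR, 737 and 523 in pSHR, 807 and 571 in pWOL, 604 and 372 in pGL2, 808 and 511 in pSUC2, 943 and 651 in pCO2, 799 and 663 in pPEP, and 725 and 1255 in pRPL11C. After quantile normalization the pRPL11C split was 859 higher and 847 lower. Without hypoxic replicate 2 the pGL2 count dropped from 976 to 619.

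The 7 measured oxygen sensing and hypoxia markers rose in all 10 root populations, 7 of 7 in each. Adjusted over the list alone the counts were also 7 of 7, which is not independent evidence, since the list was chosen for its hypoxia response. Their medians ran from 5.59 in p35S to 6.67 in pPEP, with camera adjusted p between 6.29e-60 and 7.48e-36. Of the 22 measured earlier reported hypoxia-induced loci, 21 rose in each root population (also 21 adjusted over the list alone, and again not independent evidence), with medians from 4.68 to 5.91. The fermentation list had 2 measured genes, pyruvate decarboxylase PDC2 and the lactate dehydrogenase gene AT4G17260, and both rose in all 10 root populations. PDC2 rose by between 2.50 (pSUC2) and 3.91 (pCO2), and AT4G17260 by between 2.76 (pCO2) and 3.68 (pPEP). Both lists of markers and the fermentation list held with the estimated correlation in all 10 populations. The heat shock and oxidative stress list had 2 measured genes of 18 listed, too few to stand for heat shock genes at large. The zinc finger gene STZ rose by between 1.80 (total RNA) and 4.19 (pSUC2). ATHSP22.0 had a median of 0.29 and was called in 1 of 10 root populations. The STZ call was lost in total RNA without hypoxic replicate 3 (1.14) and in p35S without hypoxic replicate 3 (1.41). Camera called this list in 5 root populations and 2 held with the estimate, p35S (median 2.24, estimated p 0.01) and pSUC2 (2.67, estimated p 0.0222). The longer list of 13 small heat shock proteins and co-chaperones had medians from 0.58 in pPEP to 1.71 in pSUC2 and was called in 9 root populations, with no call at the estimated correlation, where the lowest adjusted p was 0.199.

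Cell wall growth genes went the other way. The fixed list of 6 (EXPA4, EXPA8, EXPA15, XTH33, COB and TUB6) had medians from −1.32 in pRPL11C to −0.74 in pWOL and was called lower in all 10 root populations. With the estimated correlation the call was lost in pCO2 (estimated p 0.0627). Counts of members that fell were 4 of 6 in pRPL11C and 1 to 3 in the others, 22 of 60 values in all, or 29 adjusted over the list alone. The root hair expansin genes EXPA7 and EXPA18 both fell in 8 root populations, and 1 of the 2 fell in pPEP and in pRPL11C. Their medians ran from −2.56 in pSCR to −0.92 in pPEP, and the 8 calls held with the estimate. EXPA18 was no longer called in p35S without control replicate 3 (−0.96) or hypoxic replicate 3 (−0.79), in pGL2 without hypoxic replicate 2 (−1.14), in pPEP without control replicate 2 (−0.76) or hypoxic replicate 1 (−1.13), or in pRPL11C without control replicate 1 (−0.73). Of the 10 genes in the longer root hair list, the median was lowest in pCO2 (−1.43), and 8 populations were called, 2 of them with the estimate. In control arrays this list lay at 9.39 in total RNA, 7.91 in p35S and from 6.86 (pPEP) to 8.69 (pCO2) in the lines. Root hair transcripts were thus present in lines of other cell types, such as pSCR (8.59). In which cells these genes fell is therefore not resolved. The gap between 3′ and 5′ actin probe sets, a sign of RNA integrity, changed under hypoxia by between −0.54 (pCO2) and 0.58 (pSCR). Its SDs between arrays in control and hypoxia were 0.20 and 0.31 in pCO2 and 0.71 and 0.94 in pSCR.

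Ribosomal protein genes had a median of −0.71 over 81 genes in pRPL11C. There 17 of 81 fell and 64 did not pass, and 18 fell adjusted over the list alone. The fixed list of 5 had a median of −0.90 in pRPL11C and of −0.54 in pSUC2. No ribosomal protein call held with the estimated correlation (estimated p 0.35 for the longer list in pRPL11C, and 0.147 and 0.271 for the fixed list in pRPL11C and pSUC2). The actin gap fell by 0.49 in pRPL11C, within its SD between arrays of 1.00 in control and 0.48 in hypoxia. The like gap of GAPDH probe sets was 0.75 ± 0.39 (SD) in control and 0.62 ± 0.14 in hypoxia. The difference between the pRPL11C and p35S responses was tested directly, and 3 probe sets were called higher and 4 lower.

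**Figure D2:**
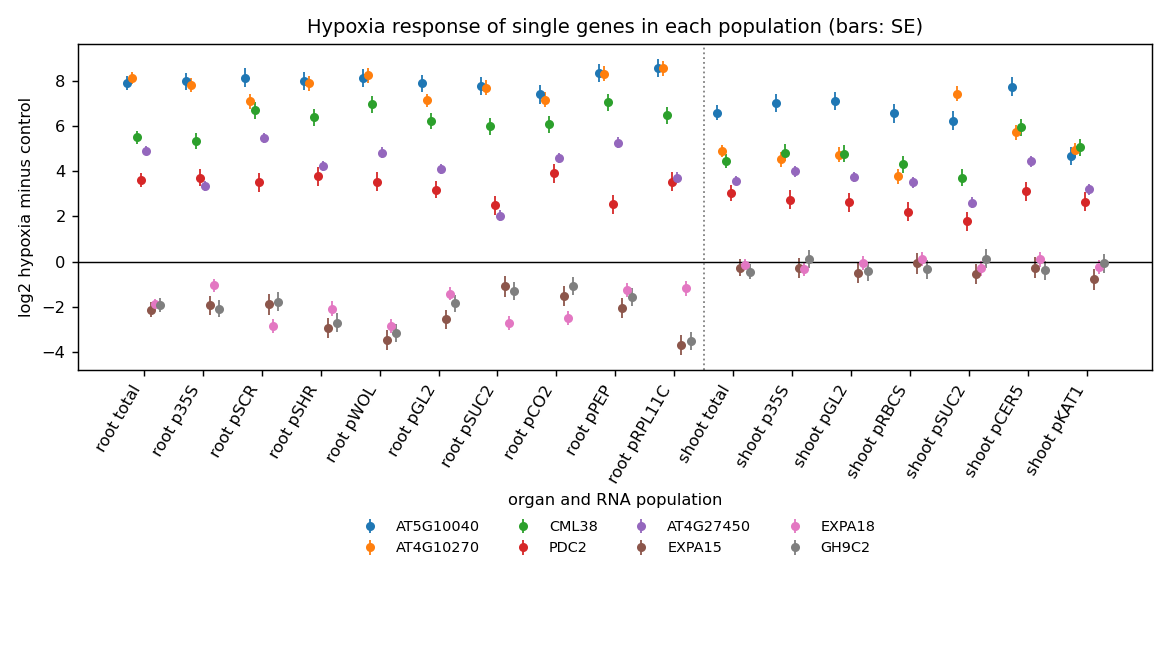
Log2 difference between hypoxia and control (vertical axis) of 8 genes in 10 root and 7 shoot populations; points are model estimates and bars their SE. AT5G10040 and AT4G10270 lie above 7 in every root population, and EXPA15 reaches −3.71 in pRPL11C.

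In shoots the question was the same. In shoot total RNA (3 arrays per condition) AT5G10040 rose by 6.60 ± 0.34 (adjusted p 2.63e-20), AT2G17850 by 5.32 ± 0.27, AT4G10270 by 4.92 ± 0.27, AT3G10040 by 4.87 ± 0.27 and AT5G66985 by 4.80 ± 0.30. AT5G10120 fell by 2.35 ± 0.29, AT5G58900 by 1.86 ± 0.23, OCT1 by 1.64 ± 0.23, and the xyloglucan-modifying gene XTH16 by 1.53 ± 0.23. In shoot p35S RNA (2 arrays per condition) AT5G10040 rose by 7.05 ± 0.41 and AT5G66985 by 5.45 ± 0.37, and AT5G10120 fell by 3.42 ± 0.35. AT5G10040 reached 7.77 ± 0.41 in pCER5, and AT4G10270 reached 7.45 ± 0.33 in pSUC2. AT5G57760 fell by 3.06 ± 0.19 in pCER5, 2.15 ± 0.19 in pGL2 and 2.11 ± 0.19 in p35S. In pCER5 AT5G62280 fell by 3.13 ± 0.30 and AT5G12050 by 3.27 ± 0.57. EXPA8 fell by 1.59 ± 0.28 in pSUC2, and AT3G44690, a gene high in pKAT1, fell there by 2.60 ± 0.28.

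Called counts in shoots were 291 higher and 120 lower in total RNA, 239 and 38 in p35S, 264 and 47 in pGL2, 239 and 57 in pRBCS, 497 and 130 in pSUC2, 442 and 320 in pCER5, and 450 and 291 in pKAT1. With 50 added, total RNA gave 204 higher and 43 lower. Single arrays moved 4 of these counts. Without hypoxic replicate 2 the count was 140 in place of 277 for p35S, 173 in place of 311 for pGL2, 171 in place of 296 for pRBCS and 356 in place of 627 for pSUC2. Without control replicate 2 the pSUC2 count was 396. The 7 hypoxia markers rose in all 7 shoot populations (7 of 7 in each, not independent evidence), with medians from 4.32 in pRBCS to 5.75 in pCER5. Of the 22 earlier reported loci, 20 rose in 6 shoot populations and 19 in pSUC2, with 20 or 21 adjusted over the list alone, and medians from 3.53 to 4.67. PDC2 rose in all 7 populations, by between 1.80 (pSUC2) and 3.11 (pCER5), though in pSUC2 the call was lost without control replicate 1 (1.74) or hypoxic replicate 2 (1.44). AT4G17260 lay between 0.87 in pCER5 and 1.71 in pSUC2. The fermentation list was called in all 7 populations and held with the estimate, with medians from 1.68 to 2.08. The cell wall growth list was lower in pSUC2 (median −0.63, estimated p 0.0208) and pCER5 (−0.43, estimated p 0.0806). STZ lay between 0.81 (pRBCS) and 3.52 (pSUC2), where the heat shock list of 2 genes was called (median 1.95, estimated p 0.0742). The 2 root hair genes had medians between −0.29 and 0.15 in shoots, where both lay near background (EXPA18 at 5.52 in control total RNA, EXPA7 lower). Ribosomal protein genes of the longer list had medians from −0.49 in pSUC2 to −0.06 in pGL2, with 6 calls of which 0 held with the estimate.

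Plastid-encoded transcripts, measured by 69 probe sets, had median hypoxia responses between −0.09 (pCO2) and 0.54 (pPEP) in roots and between −0.36 (pKAT1) and 0.60 (pCER5) in shoots, and no call held with the estimate. Camera called the fixed glycolysis list of 3 genes once, in shoot pKAT1 (median 0.54, estimated p 0.223), and the longer one of 15 genes in 6 root and 7 shoot populations (medians −0.07 to 0.46), with no call at the estimate. Mitochondrial respiratory chain genes (30 measured) had medians from −0.60 to 0.07 in roots and −0.25 to 0.06 in shoots, replication-dependent histones (9) from 0.01 to 0.72 and −0.13 to 0.43, and root cortex genes (4) from −0.07 to 0.63 and 0.09 to 0.67. None of these calls held. The same was true of the endodermal barrier list (10 genes, medians −0.35 to 0.59 in roots and −0.19 to −0.01 in shoots), of the promoter genes of the lines (2 genes, 0.19 to 1.05 and −0.54 to 0.25) and of the longer photosynthesis list (13 genes, −0.34 to 0.18 and −0.11 to 0.32). Seed maturation genes (26) had medians from −0.12 to 0.26 in roots and −0.26 to 0.12 in shoots. Camera called 0 tests for the lists of cell cycle (3 genes), guard cell lineage (4), phloem (2), photosynthesis and mesophyll (3), non-hair epidermis and trichome (2) and cuticle (3). Genes tested singly were EIN3, between −0.89 and 0.26, MCCA of leucine breakdown, between 0.84 and 3.17 in roots and 0.25 and 0.79 in shoots, and GSO1, between −0.69 and 0.50.

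**Figure D3:**
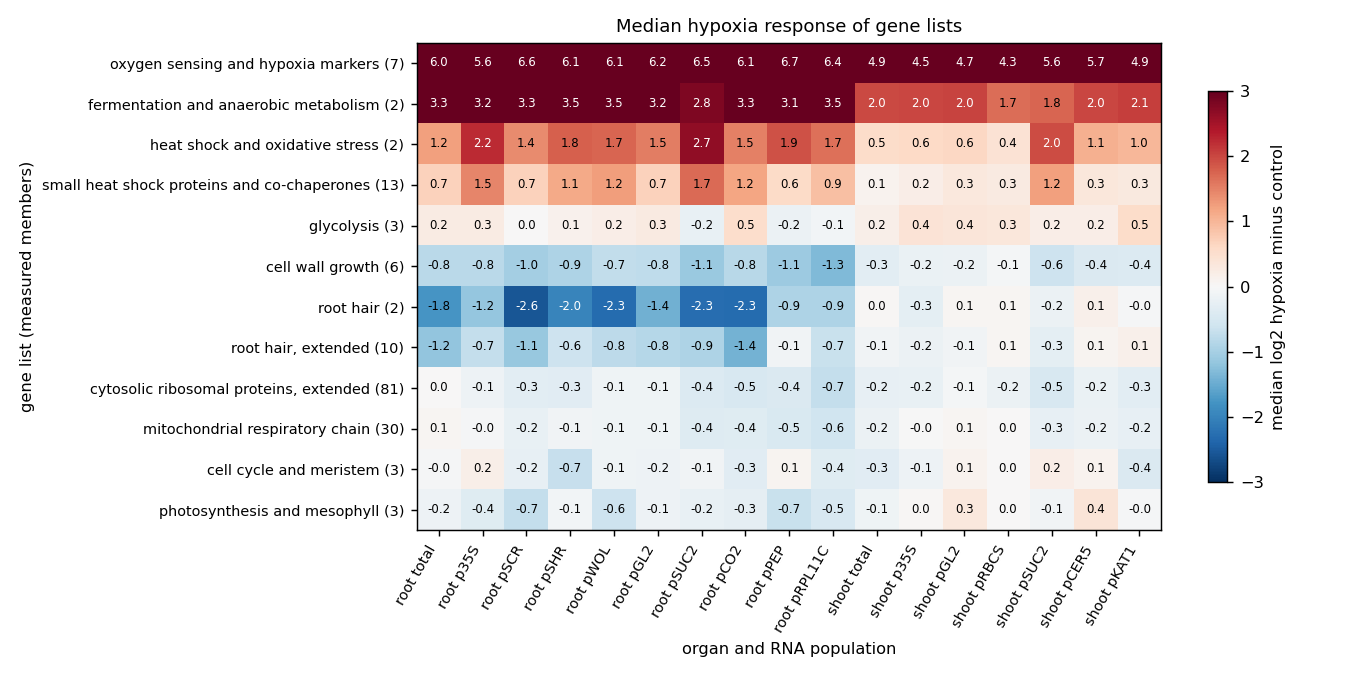
Median log2 difference between hypoxia and control (colour and number) of 12 gene lists, with the measured members in parentheses, in 10 root and 7 shoot populations. Hypoxia markers range from 4.3 to 6.7, and cell wall growth genes are negative in every root population.

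Which genes responded in every population was asked next. In all 17 populations 63 probe sets were higher, 30 of them with 1 gene, and 0 were lower. The largest median responses belonged to AT5G10040 (7.79), AT4G10270 (7.18), AT4G24110 (6.17), AT3G10040 (6.08), CML38 (5.95), AT4G33560 (5.85), AT1G19530 (5.80) and AT3G27220 (5.68). PDC2 (3.11), the lipocalin gene TIL (2.64) and FHL (2.63) were also among them. In the 10 root populations 238 probe sets were higher and 18 lower. The transcription factor gene WRKY22 had a median of 5.48, ARL, which regulates organ size, of 4.41 and GAT1_2.1 of 4.07. The 8 lower genes were AT3G50300 (median −2.40), AT3G45700 (−2.33), AT1G34510 (−2.20), AT1G08280 (−2.19), EXPA18 (−1.99), AT4G25250 (−1.62), AT2G32430 (−1.53) and AT1G68710 (−1.44). In the 7 shoot populations 104 probe sets were higher and 3 lower, among them PYE, a regulator of iron deficiency responses (median 2.29), and AT5G58900 (−1.72). With calls independent between populations at most 3.13e-09 would be expected in each case. The populations share treatment, organs and model, so independence could not hold and this figure does not test for a shared response. These counts rest on few arrays: without replicate 2 of every group they were 72 and 1 in roots, 24 and 1 in shoots and 20 in all populations, and without replicate 1 they were 121 and 3, 39 and 0, and 29. Without replicate 3 the root lower count was 6.

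A further comparison set polysomal RNA of p35S plants against total RNA of plants of that line, to ask which transcripts are over- or under-represented on tagged ribosomes. Plastid-encoded transcripts, which are translated on plastid ribosomes, were lower in polysomal RNA. In shoots 67 of 69 fell under each condition, with medians of −3.68 in air and −3.54 under hypoxia. In roots 40 and 39 fell, with medians of −1.55 and −1.53. All 4 list calls held with the estimate (estimated p 3.27e-06 in shoots and 0.0466 in roots). The list was made after the contrasts were seen, so these p-values are not independent evidence. Largest were the differences of rpl22 (−5.88 ± 0.44, 2 polysomal and 3 total arrays) and rpl16 (−5.43 ± 0.67) in control shoots, and of atpB (−3.64 ± 0.41, 3 and 4 arrays) and rps3 (−3.34 ± 0.32) in control roots. Plastid-encoded medians were 10.86 in control shoot total RNA and 6.74 in p35S, and 6.94 and 5.21 in roots. Among nuclear genes AT1G50060 was higher in control roots by 2.77 ± 0.23 and in hypoxic roots by 2.89 ± 0.28, AT4G09890 by 2.73 ± 0.31 in control roots, and the defensin-like gene PDF2.1 by 2.37 ± 0.37 in hypoxic roots. AT1G66100 was higher in shoots, by 1.83 ± 0.25 in air and 2.06 ± 0.25 under hypoxia. Root hair genes EXPA7 and EXPA18 were lower in polysomal RNA of roots (medians −2.02 and −1.41), 2 of 2 under each condition, and the calls held (estimated p 0.00541 and 0.0305). Of the longer root hair list 6 of 10 genes were lower in control roots (median −1.67, estimated p 0.0315) and 6 of 10 in hypoxic roots (−1.22), where the list call was lost (estimated p 0.126). In control roots the root cortex list had a median of −1.26 (estimated p 0.0315). Whether p35S tags all root cell types evenly was not tested, so these differences need not reflect ribosome loading alone.

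Called counts were 659 higher and 713 lower in control roots, 530 and 530 in hypoxic roots, 202 and 509 in control shoots, and 427 and 378 in hypoxic shoots. After quantile normalization control roots had 752 higher and 699 lower, and control shoots 412 and 368. With 50 added the counts were 345 and 382 in control roots and 267 and 287 in hypoxic roots. In control shoots they were then 90 and 231, and in hypoxic shoots 236 and 190. Without control total replicate 1 the control shoot count rose from 711 to 1129. Of 13 photosynthesis genes encoded in the nucleus 4 were higher in polysomal RNA of control and 2 of hypoxic roots (medians 0.84 and 0.61), and of the 3 fixed ones 1 and 0 (0.87 and 0.86). These list calls were lost with the estimate (estimated p 0.224 and 0.291, and 0.157 and 0.291). Of 30 mitochondrial respiratory chain genes 1 was higher in control and 3 in hypoxic shoots (medians 0.52 and 0.64), and the list calls were lost (estimated p 0.157 and 0.107). Histones (0.46 to 0.76), seed maturation genes (0.07 to 0.31) and earlier reported hypoxia loci (0.19 to 0.48) were called higher in 4, 4 and 3 of the 4 settings and lost each call with the estimate. Ribosomal protein genes had medians of −0.21 and −0.33 in roots and 0.28 and 0.29 in shoots, also lost, as were root cortex in hypoxic roots (−0.60) and control shoots (−0.79), the endodermal barrier in control roots (−0.47) and promoter genes in control shoots (−1.10). The actin gap was 3.10 ± 0.86 (SD) in control root total RNA and 3.54 ± 0.52 in p35S.

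Whether hypoxia shifts transcripts between the polysomal and the total pool was tested as an interaction. In roots AT3G07070 was shifted towards polysomal RNA by 1.78 ± 0.34 (adjusted p 0.0179), and AT4G30380 (−2.27 ± 0.42), AT4G27450 (−1.58 ± 0.28), AT1G12320 (−1.54 ± 0.28) and AT5G51470 (−1.22 ± 0.22) were shifted away from it. An unadjusted p under 0.05 was found for 674 of 22746 probe sets, a smaller share than chance alone gives. The test was thus cautious here, and few calls do not show that loading was unchanged. In all 2 probe sets were called higher and 4 lower. This count was 8 higher and 4 lower after quantile normalization and 6 and 4 with 50 added. It was 0 with root arrays fitted alone, 0 without hypoxic p35S replicate 3 and 3 without control p35S replicate 1, 10 without control p35S replicate 3, 13 without control total replicate 1, 14 without hypoxic p35S replicate 1, and 15 without control total replicate 4 or hypoxic total replicate 1. Without hypoxic p35S replicate 3 the values were 1.575 for AT3G07070, −2.21 for AT4G30380, −1.41 for AT4G27450, −1.55 for AT1G12320 and −1.33 for AT5G51470. The call of AT3G07070 was also lost without control total replicate 2 (1.72) or 3 (1.69), hypoxic total replicate 4 (1.73) or control p35S replicate 1 (1.78) or 2 (1.58), that of AT4G30380 without control p35S replicate 1 (−2.19), that of AT1G12320 without control p35S replicate 2 (−1.39) and that of AT5G51470 without hypoxic p35S replicate 1 (−1.115). Hypoxia markers had a median of −0.40 in this root contrast (camera adjusted p 0.00654, estimated p 0.596). In shoots 563 probe sets had an unadjusted p under 0.05, again a smaller share than chance gives. A lack of calls thus does not show a lack of shifts there either. For shoots limma called 0 probe sets. With 50 added it called 1, and without hypoxic total replicate 1 it called 1. Of 52 list tests 7 were called and 0 held with the estimated correlation.

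The next comparison asked which transcripts each promoter line enriches relative to p35S in air. All lines of an organ share the p35S control arrays. In root pSCR (2 arrays against 3 of p35S) the defensin-like gene PDF2.5 was higher by 4.44 ± 0.24 (adjusted p 7.17e-19), AT1G73620 by 3.74 ± 0.34 and XTH16 by 3.40 ± 0.26, while XTH20 was lower by −3.28 ± 0.29. Genes of the endodermal barrier were higher in pSCR, 10 of 10, with a median of 2.46 (camera adjusted p 3.82e-18, estimated p 0.000276), and the receptor kinase gene GSO1, which guides Casparian strip formation, was higher by 2.65 ± 0.26. In pPEP 7 of these 10 were lower (median −2.05, estimated p 0.282). AT1G09750, the gene whose promoter drives pPEP, was higher in pPEP by 4.29 ± 0.36, as were CYP71B26 (3.68 ± 0.31), DLAH (3.57 ± 0.38) and AT1G62510 (3.46 ± 0.32). Root cortex genes had a median of 2.38 in pPEP, where 3 of 4 were higher (estimated p 0.0253), and all 3 cell cycle genes were lower, PRL by −1.54 ± 0.18, AUR1 by −1.99 ± 0.25 and AUR2 by −1.57 ± 0.33 (estimated p 0.0357 for the list). AUR2 was −0.99 and not called without control pPEP replicate 2. AT1G62500, the gene of the pCO2 promoter, differed by 0.16 ± 0.21 in pCO2 (adjusted p 0.693).

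Other root lines showed further genes. AT3G61210 was higher in pSUC2 by 4.00 ± 0.22 and the sucrose phosphate synthase gene ATSPS4F by 3.64 ± 0.38. AT1G73620 was higher in pCO2 by 4.13 ± 0.34, AT2G25590 in pGL2 by 3.48 ± 0.29, and PDF2.5 in pWOL by 2.57 ± 0.24. AT1G50060 was lower by −5.49 ± 0.28 in pPEP, −4.95 ± 0.25 in pGL2 and −4.87 ± 0.28 in pWOL. AT5G35200 was higher in pSHR by 2.73 ± 0.31, in pWOL by 3.25 ± 0.31, in pSultr2;2 by 3.59 ± 0.31 and in pCO2 by 3.96 ± 0.31, and its control level was 9.88 in root total RNA, 10.87 in p35S and 14.83 in pCO2. Against the mean of the other lines its pSHR difference was −0.21. Camera called plastid-encoded transcripts higher than in p35S in 7 of 9 root lines, with medians from 0.46 in pWOL to 1.64 in pCO2 (40 of 69 called), and lower in pRPL11C (−0.12, 0 of 69 called), and 0 of these calls held with the estimate. In pPEP the list was not called (0.22, adjusted p 0.239). The actin gap was 2.72 ± 0.07 (SD) in pWOL, 2.83 ± 0.71 in pSCR, 3.54 ± 0.52 in p35S and 4.16 ± 0.20 in pCO2.

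Called counts in roots were 1047 higher and 971 lower in pSCR, 281 and 190 in pSHR, 492 and 159 in pWOL, 828 and 376 in pGL2, 983 and 871 in pSUC2, 554 and 322 in pSultr2;2, 1302 and 757 in pCO2, 1742 and 1581 in pPEP, and 5 and 13 in pRPL11C. Quantile normalization changed the split to 956 and 1071 in pSCR, 885 and 967 in pSUC2, 1516 and 1697 in pPEP, 233 and 249 in pSHR, 368 and 202 in pWOL, 390 and 414 in pSultr2;2 and 3 and 14 in pRPL11C, and adding 50 gave 4 and 6 in pRPL11C. AT5G35450 was higher in pRPL11C by 1.64 ± 0.25, a call lost without its control replicate 1 (1.565), and AT3G02480 was lower by −2.66 ± 0.36, against 0.31 with the mean of the other lines as reference. The pRPL11C count of 18 fell to 3 without its control replicate 1 and to 6 without its control replicate 2. With the replicate number as a block, which here joins like-numbered control arrays of different populations, it was 31. Against the mean of the other lines the counts were 1034 in pRPL11C, 1088 in pSCR, 129 in pWOL, 225 in pGL2, 808 in pSUC2, 211 in pSultr2;2 and 654 in pCO2.

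In shoots the promoter lines differed in similar ways. In pSUC2 (2 arrays against 2) AT1G01390 was higher by 5.46 ± 0.17. In pCER5 AT3G21950 was higher by 2.95 ± 0.22 and AT4G19380 by 2.94 ± 0.26, while LCR68 was lower by −5.01 ± 0.21. Root cortex list members were lower in pSUC2 (median −1.70) and pCER5 (−2.08), 4 of 4 in each (estimated p 0.032 and 0.0129). In pKAT1 AT3G44690 was higher by 5.96 ± 0.28, the stomatal transcription factor gene FMA by 2.81 ± 0.20 and AT1G22690 by 3.10 ± 0.22, whereas SPCH (−0.38 ± 0.20) and MUTE (−0.05 ± 0.22) were not called. The guard cell list had a median of 1.38 in pKAT1 (camera adjusted p 0.00393, estimated p 0.0989). AT2G33850 was higher in pGL2 by 2.84 ± 0.29. AT5G10120 was lower in pRBCS by −4.34 ± 0.35.

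Plastid-encoded transcripts, also a list made after the contrasts, were much higher in pKAT1 than in p35S, 65 of 69 with a median of 3.69 (estimated p 0.000357). Their control medians were 10.54 in pKAT1, 10.86 in total RNA, 8.10 in pCER5, 7.83 in pGL2, 7.54 in pRBCS, 6.98 in pSUC2, 6.77 in pSultr2;2 and 6.74 in p35S. The gene rpl22 was higher in pKAT1 by 6.35 ± 0.48. Among nuclear genes AT3G28530 was higher by 6.25 ± 0.41 and AT1G13880 by 6.02 ± 0.28. Their levels in shoot total RNA were 5.92 and 6.76, against 11.55 and 13.64 in pKAT1. Seed maturation genes, a list made after these contrasts were seen, had medians from −1.69 in pGL2 to −1.18 in pKAT1 against p35S, with 96 of 156 values called. Over the 19 of 26 members not named before, the medians ran from −0.61 in pRBCS to −1.18 in pCER5. AT3G02480 was lower by −5.33 ± 0.40 in pGL2 and −5.41 ± 0.40 in pSultr2;2, and AtLEA4-1, a late embryogenesis gene, by −3.99 ± 0.32 in pGL2 and −4.08 ± 0.32 in pRBCS.

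Called counts in shoots were 138 higher and 130 lower in pGL2, 19 and 236 in pRBCS, 1529 and 1419 in pSUC2, 616 and 328 in pSultr2;2, 1949 and 1363 in pCER5, and 1158 and 306 in pKAT1. Quantile normalization gave 1361 and 1653 in pSUC2, 382 and 413 in pSultr2;2, 1428 and 1680 in pCER5, and 949 and 493 in pKAT1. Without control p35S replicate 1 the counts were 171 in place of 268 for pGL2 and 156 in place of 255 for pRBCS. Against the mean of the other lines they were 178 in pGL2, 1230 in pRBCS and 322 in pSultr2;2. The actin gap was 2.52 ± 0.64 (SD) in pSUC2, 3.39 ± 0.08 in p35S and 3.87 ± 0.38 in pKAT1. Of the other lists tested on the 15 enrichment contrasts, calls lost with the estimated correlation were 10 for ribosomal proteins of the longer list (medians −0.72 to 0.57) and 2 for the fixed one, 9 for photosynthesis of the longer list (−1.49 to 0.42), 9 for seed maturation in roots (−0.44 to −0.25), 7 for the longer root hair list (−1.02 to 0.91) and 1 for the fixed one, 5 for the endodermal barrier in shoots (−0.77 to −0.20), 4 for histones (−0.77 to −0.07), 3 for cell wall growth (−0.84 to 0.62), 3 for promoter genes (−1.59 to 2.31), 2 for each glycolysis list, 2 for the respiratory chain, 2 for earlier reported loci and 1 for cuticle (0.87 in shoot pGL2). Lists of phloem, fermentation, heat shock, non-hair epidermis, hypoxia markers and the fixed photosynthesis list gave 0 camera calls there.

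**Figure D4:**
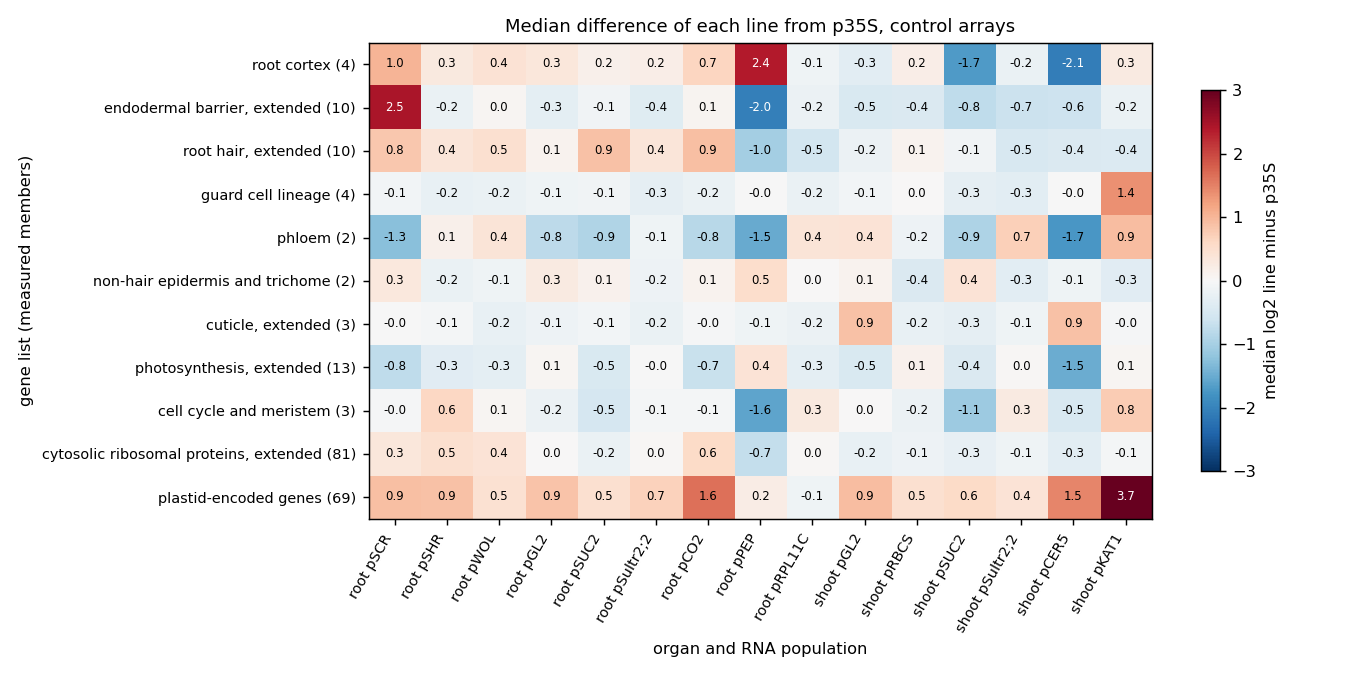
Median log2 difference of each promoter line from p35S on control arrays (colour and number) for 11 gene lists, with the measured members in parentheses. The endodermal barrier list stands at 2.5 in root pSCR and plastid-encoded genes at 3.7 in shoot pKAT1.

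Differences between root and shoot responses were tested as interactions in the 4 populations measured in both organs. The auxin-conjugating enzyme gene GH3.3 responded more in roots, by 4.19 ± 0.44 in total RNA (adjusted p 6.93e-09) and 3.90 ± 0.54 in p35S. AT2G41730 did so by 4.04 ± 0.54 and 3.79 ± 0.65, ARL by 3.50 ± 0.43 in p35S, AT4G37240 by 3.68 ± 0.39 in pGL2 and AT1G33050 by 3.92 ± 0.50 in pSUC2. AT5G20790 responded less in roots than in shoots, by −3.42 ± 0.44 in total RNA and −3.08 ± 0.53 in p35S. AT3G45700 had −3.58 in root and −0.42 in shoot pSUC2, a difference of −3.16 ± 0.35, from control levels of 11.10 and 6.41. In shoot pKAT1, where its control level was 8.50, it fell by 1.90 ± 0.25 (adjusted p 2.10e-07). In total RNA the 7 hypoxia markers had a median difference of 1.34 (estimated p 0.0213) with 4 of 7 called, which is not independent evidence. Their calls in p35S (0.81), pGL2 (0.99) and pSUC2 (1.00) were lost (estimated p 0.219, 0.0661 and 0.444). Fermentation genes had 1.24 in p35S (estimated p 0.0415), 1.16 in pGL2, where the call was lost (estimated p 0.0661), and 1.05 in pSUC2, not called (adjusted p 0.0578). Called counts were 197 higher and 169 lower in total RNA, 81 and 58 in p35S, 180 and 148 in pGL2, and 254 and 226 in pSUC2, and quantile normalization gave 187 and 223 in total RNA. The p35S count of 139 was 231 without hypoxic root replicate 1, 90 without hypoxic root replicate 3, 85 without control shoot replicate 2 and 88 without hypoxic shoot replicate 2. The pGL2 count of 328 was 161 without hypoxic root replicate 2, and without single other arrays 197, 203 or 213. The pSUC2 count of 480 was 247 without control shoot replicate 2 and at most 378 without any single array. With the replicate number as a block the counts were 113 higher and 124 lower in p35S, 238 and 254 in pGL2, and 421 and 472 in pSUC2.

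Among the promoter lines other than p35S the F-test asked whether hypoxia responses differ. In roots AT1G33050 spanned 4.47, from −0.13 in pRPL11C to 4.33 in pCO2 (adjusted p 2.06e-06), and AT5G64870 spanned 3.85, from 0.36 in pSCR to 4.21 in pSUC2. In shoots AT3G03270 spanned 4.03, from 0.58 in pSUC2 to 4.62 in pCER5 (adjusted p 2.34e-06), and AT4G10270 spanned 3.66, from 3.79 in pRBCS to 7.45 in pSUC2. Called were 772 probe sets in roots and 294 in shoots. The root count was 495 without control pRPL11C replicate 2, with each organ fitted alone the counts were 311 and 157, and with the replicate number as a block 1771 and 522.

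**Figure D5:**
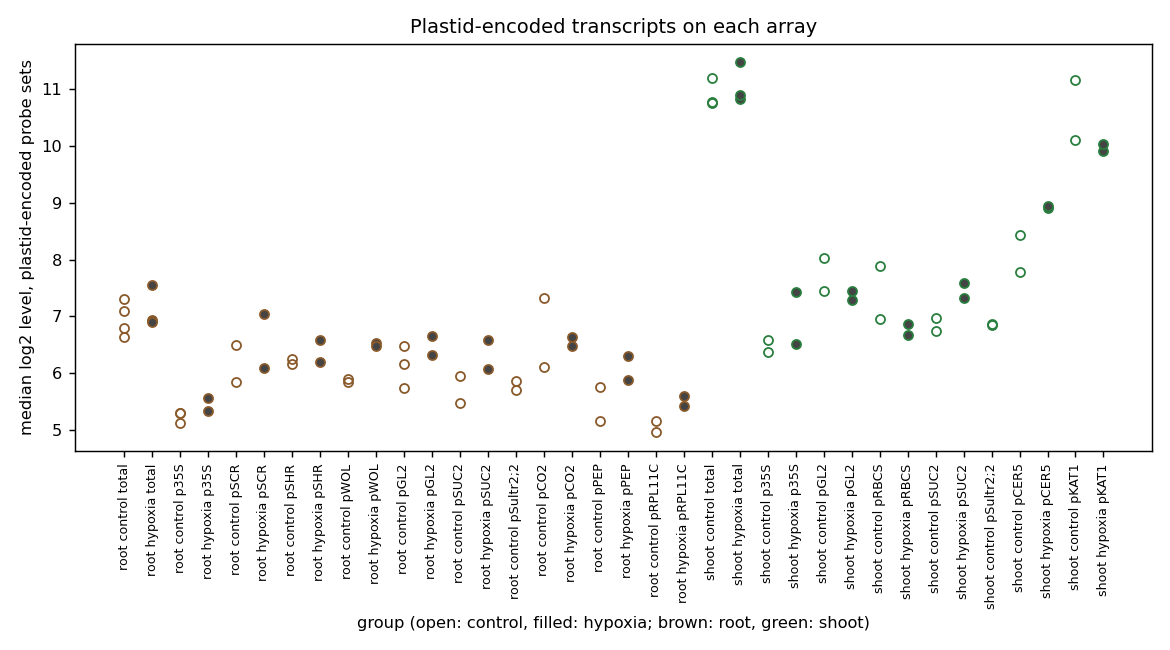
Median log2 level of 69 plastid-encoded probe sets on each array (points) by group; open points are control and filled points hypoxic arrays, brown for roots and green for shoots. Shoot total RNA and shoot pKAT1 lie near 10 to 11, and shoot p35S near 7.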

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

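Gene list medians were compared across the 4 control arrays of root total RNA, the only group large enough for this test. The mean, median, actin gap, GAPDH gap and plastid-encoded median of each array were compared as well. Of the tests in this part, the count without total RNA replicate 4 was chosen after the results were seen.

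In root total RNA, 33 measures were tested, and in 5 of them a single array lay far from the other 3, beyond Dixon's 95% limit. Chance gives about 1 in 20 for a single measure. The measures come from the same arrays and some lists share members, so they are not independent. Replicate 4 had an actin 3′ minus 5′ gap of 1.83, against 3.42 to 3.73 in the others, a median of 8.88 for the low-energy list (the single gene MCCA) and of 8.91 for replication-dependent histones. The hypoxic total RNA array numbered 4 also had a low gap, 1.82 against 3.71 and 3.35. Deviations of the control and hypoxic arrays numbered 4 correlated at 0.72, so the low gap is not that of a lone array. Replicate 3 had a photosynthesis and mesophyll median of 6.34, and replicate 2 a median of 9.82 for the longer root hair list. Without replicate 4 of both conditions the hypoxia count of root total RNA was 644, against 766 with these arrays.

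Root and shoot responses to hypoxia differed by the interaction test in 366 probe sets of total RNA, 139 of p35S, 328 of pGL2 and 480 of pSUC2. In total RNA the difference (root minus shoot response) was 4.19 for GH3.3, 4.04 for AT2G41730 and 3.50 for AT5G39580, and −3.42 for AT5G20790, −2.64 for AT4G25250 and −2.40 for AT1G72920. In p35S it was 3.90 for GH3.3, 3.79 for AT2G41730, 3.50 for ARL, −3.24 for AT1G72920, −3.08 for AT5G20790 and −2.86 for AT3G29970. Without hypoxic shoot replicate 2 the p35S call of AT1G72920 was lost (−1.91). In pGL2 it was 3.68 for AT4G37240, 3.61 for AT4G24110, 3.43 for AT4G14980, −2.77 for AT1G12320, −2.76 for AT5G20790 and −2.63 for AT5G01790, and without hypoxic shoot replicate 2 the call of AT5G20790 was lost (−1.85). In pSUC2 it was 3.92 for AT1G33050, 3.61 for AT4G30380, 3.53 for AT5G39580, −3.16 for AT3G45700, −2.97 for the late embryogenesis gene M17 and −2.85 for AT1G34510, whose call was lost without control root replicate 1 (−2.43). In the shoot control arrays of the same populations AT4G25250 lay at 4.49 and AT1G12320 at 4.77, near background, and AT1G34510 lower than AT1G12320, so for these 3 genes a fall like that in roots could not be seen there. The p35S count was 85 without control shoot replicate 2 and 231 without hypoxic root replicate 1, the pGL2 count 161 without hypoxic root replicate 2, and the pSUC2 count 247 without control shoot replicate 2.

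Among gene lists, the median difference between root and shoot responses in total RNA was 1.31 for earlier reported hypoxia loci (estimated p 0.0212), 1.305 for fermentation (0.0415), 1.34 for hypoxia markers (0.0213), −1.81 for the root hair genes EXPA7 and EXPA18 (0.000568) and −1.25 for the longer root hair list (0.0118). Fermentation had 1.24 in p35S, earlier reported loci 0.95 in pGL2, and root hair genes −1.49 in pGL2 and −2.10 in pSUC2. With the estimated correlation the calls of earlier reported loci were lost in p35S (0.71, estimated p 0.0974) and pSUC2 (0.96, 0.0914), that of root hair genes in p35S (−0.87, 0.0661), and those of the longer root hair list in p35S (−0.74, 0.14), pGL2 (−0.77, 0.326) and pSUC2 (−0.89, 0.189). In control shoot total RNA EXPA18 lay at 5.52 and EXPA7 lower, near background, as did the longer root hair list (median 5.38), where a fall could not be seen, so the root hair differences say nothing about the response of shoots. The lists of markers and earlier reported loci were chosen for their hypoxia response.

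The hypoxia response differed between polysomal and total RNA of roots in 6 probe sets: AT3G07070 (1.78), AT4G30380 (−2.27), AT4G27450 (−1.58), AT1G12320 (−1.54), AT5G51470 (−1.22) and 1 more. Without hypoxic p35S replicate 3, or with root arrays fitted alone, the count was 0. Among promoter lines other than p35S the responses differed in 772 probe sets in roots and 294 in shoots. The widest spans were 4.47 for AT1G33050, 3.85 for AT5G64870 and 3.72 for AT2G15880 in roots, and 4.03 for AT3G03270, 3.70 for the plastid-encoded petL and 3.66 for AT4G10270 in shoots. Without control pRPL11C replicate 2 the root count was 495.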

How the results depend on the processing

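Omitting a whole total RNA replicate, crossing the replicate numbers in pRPL11C, and omitting plastid-encoded probe sets were tests chosen after seeing the data. Counts are called probe sets; one that stays within 1.5 times its value is taken as kept, the cause was not tested where it is not, and the array signal limits weak probe sets. Of 52 counts under quantile normalization 51 were kept, and the root loading count became 12. With dim probe sets left out all 50 were kept. With 50 added, which shrinks differences at low signal by its construction, 34 of 50 moved: hypoxia root total 480, pSCR 792, pSHR 805, pGL2 623, pSUC2 873, pCO2 1052 and pRPL11C 1271, shoot total 247, pRBCS 197, pSUC2 385, pCER5 496 and pKAT1 440; polysomal 727 in control and 554 in hypoxic roots, 321 in control and 426 in hypoxic shoots; loading 10 in roots and 1 in shoots; enrichment root pSCR 1264, pSHR 229, pWOL 352, pGL2 701, pSUC2 1164, pSultr2;2 482, pCO2 1192, pPEP 2210 and pRPL11C 10, shoot pGL2 149, pRBCS 135, pSultr2;2 478, pCER5 2162 and pKAT1 845; lower in every population 10 in roots and 0 in shoots. With each organ fitted alone, root loading was 0 and the F-test counts were 311 in roots and 157 in shoots. With a replicate block the organ counts were 237 in p35S and 893 in pSUC2, the F-test counts 1771 in roots and 522 in shoots, lower in every shoot population 5, shoot loading 1 and root pRPL11C enrichment 31. With the numbers crossed, the pRPL11C hypoxia count was 2041 (754 higher, 1287 lower). Against the mean of the other lines, enrichment counts were root pSCR 1088, pWOL 129, pGL2 225, pSUC2 808, pSultr2;2 211, pCO2 654 and pRPL11C 1034, and shoot pGL2 178, pRBCS 1230 and pSultr2;2 322. Without shoot total replicate 3 shoot loading was 1, and omitting plastid-encoded probe sets moved 0 of 15. Arrays were left out 1 at a time or, for the counts in every population, 1 replicate number of all groups at a time. A lone array is then assumed to vary like the other groups. In all this moved 46 of 305 values over 21 counts. Lowest and highest were, for hypoxia, root p35S 313 and 1002, pGL2 619 and 1076, shoot p35S 140 and 377, pGL2 173 and 312, pRBCS 171 and 354, pSUC2 356 and 627; polysomal control shoot 495 and 1129; loading root 0 and 15, shoot 0 and 1; enrichment root pRPL11C 3 and 20, shoot pGL2 171 and 257, pRBCS 156 and 227; organ p35S 85 and 231, pGL2 161 and 328, pSUC2 247 and 378; F-test root 495 and 881; every root population 72 and 229 higher, 1 and 17 lower; every shoot population 24 and 106 higher, 0 and 3 lower; every population 20 and 64 higher. Of 696 named gene values 679 kept their call under quantile normalization, 627 with 50 added and 692 with the block, and 3180 of 3443 did without 1 array. Against the mean of the other lines 130 of 243 were kept and 20 reversed: AT5G35200 in root pSHR (−0.21) and shoot pGL2 (−0.065), AT1G50060 in root pSHR (0.34), pSUC2 (0.12) and pCO2 (0.43), AT1G52050 in pSHR (0.063), AT3G02480 in root pRPL11C (0.31) and shoot pKAT1 (2.05), BGLU19 in pRPL11C (0.26), AT1G13880 in shoot pGL2 (−0.12) and pRBCS (−2.49), AT1G19480 (−1.86), psbH (−0.42) and CAF1 (−1.17) in pRBCS, AT2G25890 (0.95) and AT4G31830 (0.24) in pKAT1, and AT1G09750 in root pSCR (−0.45), pSHR (−0.46), pWOL (−0.24) and pSultr2;2 (−0.21).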

Other observations

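The tests on plastid-encoded transcripts, on seed maturation transcripts, and on scaling and RNA integrity in pRPL11C were chosen after the results were seen.

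Plastid-encoded transcripts were high in the polysomal RNA of shoot pKAT1 (median 10.54, against 6.74 in p35S). Were cells richer in chloroplasts the cause, pRBCS, of mesophyll, should lie at or above pKAT1. The control median of pRBCS minus that of pKAT1 was −2.99, with SDs between arrays of 0.66 and 0.76. This argues against that cause for these plastid-encoded transcripts. But these transcripts are translated on plastid ribosomes, so their level need not measure chloroplasts in the tagged cells. Carryover of RNA not bound to tagged ribosomes may contribute: 149 nuclear probe sets that were lower in p35S than in total RNA of hypoxic shoots had a median of 1.17 in pKAT1 minus p35S, against 1.12 in total RNA and 0.15 to 0.57 in the other lines. The 271 probe sets higher in p35S than in total RNA did not set pKAT1 apart, with −0.32 in pKAT1, −0.94 in total RNA and −0.08 to −0.49 in the other lines, so carryover stays open.

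Seed maturation transcripts were high in shoot p35S (6.57) and total RNA (6.53), which come from plants of that line, and low in other shoot lines (4.81 to 4.98, pKAT1 5.58). Seed transcripts present only in the p35S plants stay open. Over all 26 members pKAT1 exceeded the highest of the other lines, pCER5, by 0.60, but over the 19 members not named before it lay at −0.92 from p35S, inside the −0.61 (pRBCS) to −1.18 (pCER5) of the others. Cells outside the domains of the other promoters cannot be told apart from this, since p35S exceeded total RNA by a median of 0.16 and both come from plants of one line.

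Root pRPL11C had more probe sets lower under hypoxia (1255) than any other root population. The deposited scaling stays open: after quantile normalization 847 were lower, with 698 in pCO2 next, and leaving out 1 array gave as few as 726 in pRPL11C (control replicate 2) and as many as 808 in pCO2 (control replicate 1). Changes in p35S that are alike in size and miss the threshold stay open for the gap to p35S. The direct test of the difference between these responses called 3 probe sets higher and 4 lower, from groups of 2 or 3 arrays. But 2142 of 22746 had an unadjusted p under 0.05, a larger share than chance alone gives. The few calls thus do not show that the responses are alike. RNA integrity stays open: over 10 root populations the change of the actin gap and the number lower had a Pearson r of −0.58 (permutation p 0.0802), a Spearman rho of −0.48 (p 0.166), and a Pearson r of −0.68 without the 2 farthest populations. The gap varied between arrays of a group, with an SD of up to 1.17 (hypoxic pSHR), so its changes are known only roughly. No biological explanation was tested for this pattern.

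Other splits of the same arrays were counted with these arrays fitted alone. Hypoxia in root total RNA called 527 probe sets and polysomal against total RNA of control roots 1296. In both 1 of 35 splits, the real one, gave as many and the highest other gave 0. In hypoxia of root total RNA the replicate numbers pair the arrays. For polysomal against total RNA the correlations of arrays with the same number were 0.01, 0.15 and 0.39, and both come from p35S plants, so shared plants are not ruled out. In each case 8 of the splits part all 3 pairs, the highest other of these gave 0, and 8 are too few for a share under 0.05. Hypoxia in shoot total RNA called 212 and pGL2 against p35S in roots 1186, where 1 of 10 splits gave as many and the highest other gave 0, and 10 splits are too few for a share under 0.05. The replicate numbers also pair the arrays of shoot total RNA (correlations 0.36, 0.22 and 0.60). In each case 4 of the 10 splits part all 3 pairs of like-numbered arrays.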
